A study of Arabidopsis thaliana with 12 samples.

How the data were processed

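Total RNA of Arabidopsis thaliana, wild type of the Columbia 0 ecotype, was measured on expression arrays in 12 samples, 6 labelled as grown in light at 80 µE and 6 labelled as light-stressed (1000 µE, 1 h). Group and number of each sample were taken from the labels. The labels give no tissue, plant age, array type, scanner or batch, and nothing states that the 6 samples of a group came from separate plants or cultures, so the p-values measure the spread between these samples, which may be technical.

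The deposited values are intensities on a linear scale, from 0 to a ceiling just under 100. How the authors made these intensities from the scans (background, scaling, filters) is not given in the sources used here, and the unit is therefore arbitrary. The table holds 3439 probes. Column medians lay between 0.115 and 0.130 in normal light and between 0.338 and 0.357 in high light, a ratio of 3.10 between the largest and the smallest, so the values had not been brought to a common median. An exact 0 stood for 396 to 470 probes per sample in normal light and for 167 to 209 in high light. The number of arrays limits the precision.

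Gene names came from the platform annotation, updated to the locus names of the RefSeq table of assembly TAIR10.1 through gene identifiers. Of the probes, 692 had 1 gene, 870 had several and 1877 were not listed. Of the 692, 690 matched the RefSeq table, and 2 kept their older name. No gene was named from a probe with several, and no coordinates are given because the sources name no genome build for the array.

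Before the data were examined it was fixed that deposited values would be kept only if the column medians lay within a factor of 1.1, and otherwise quantile-normalised between arrays, as was done here. Values of 0 were then set to the lowest positive value of the table, 9.02e-06, after the scaling and on every scale, so that a 0 has 1 value in all samples. Log2 values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, without a fold threshold), with Benjamini-Hochberg adjustment over the 3439 probes and a threshold of 0.05. Probes of 1 gene were tested separately. A rule fixed in advance would have averaged 3 pairs of samples, the same numbers in both groups, if they were alike enough. For every pair, the SD of the log2 differences had to be under 0.5 of the median SD of the other sample pairs of the group. The rule did not name the pairs, and it was checked for samples 1 and 2, 3 and 4, and 5 and 6. The smallest ratio was 0.669, so by this rule the 12 samples entered as replicates. The averaged fit of 3 against 3 is given beside the total of calls, for named genes that lost their call, and for some that kept it. Other adjusted p values of single genes come from the 12-sample fit and would be too small if the pairs are repeats. The SDs include the zeros set to the lowest positive value, which widen all differences. The rule can therefore miss repeats and does not show that the 12 samples are independent.

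Of 22 gene lists with 376 genes fixed in advance, 8 lists had members among the named probes, 16 genes in all, and 1 list reached the minimum of 4 measured members for a set test (camera with a preset correlation of 0.01, with fry and an estimated correlation beside it). A further 7 lists were written after the probe names were known, and after the intensities of the brightest probes had been seen, but before any test. Named genes are the 10 largest rises and the 10 largest falls among named probes with an adjusted p under 0.05 and no overlap between the groups, plus the 2 called members of each list with the largest change. Because values at 0 have no order, the ranking was limited to probes above 0 in all 12 samples, which the rule fixed in advance did not state. Other called members of the lists, and the members of the fixed lists above 0 in all samples, are also given. The rule further named a set of marker genes of light stress, among them ELIP1 and APX2, of which none was measured by a probe of a single gene.

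On simulated data with the means, SDs and zeros of the normal light samples and 200 changed probes, this comparison of 6 with 6 samples over 3439 probes recovered 38.0% of changes of 1 and 76.0% of changes of 2 on the log2 scale, with 9 false calls (7.3% of calls). The simulated samples were independent, with no likeness of pairs and no difference in medians or zeros between the groups. These shares therefore do not give the recovery or the false calls of the real comparison.

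The alternatives fixed in advance were 3 other scalings (deposited values, a common median, cyclic loess), a filter on the dimmest 25% of probes, an offset before log2 of 0.0056, the 10th percentile of all values, subtraction of a 1% background, other limma settings, array weights, sample numbers as a block, averaged or correlated pairs, each sample left out, an exact rank-sum test and a fold threshold of 2. Added after the data were seen were a floor of 0.05, the 2233 probes above 0 in all samples, and the fit without samples 5 and 6 of both groups. Figures show quantile-normalised values unless stated otherwise.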

Results

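Gene expression in wild-type Arabidopsis plants labelled as exposed to high light (1000 µE) for 1 h was compared with that in plants grown in normal light (80 µE), with 6 array samples in each group. The titles give 0 h for the normal light samples and 1 h of high light for the others. The comparison therefore asks which transcripts differ after 1 h of high light from those at 0 h. No sample is labelled as kept in normal light for that hour, so effects of light and of elapsed time cannot be told apart. Each sample gave intensities for 3439 probes, of which 692 name a single gene. The mean intensity per sample was 0.880 ± 0.023 (SD, n = 6) in normal light and 1.03 ± 0.016 (SD, n = 6) in high light.

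The deposited intensities differed between the groups over most of their range. The median per sample was 0.124 ± 0.0066 in normal light and 0.348 ± 0.0067 in high light (mean ± SD, n = 6), and no sample of one group reached the range of the other. The 99th percentile went the other way, with 13.7 ± 0.684 in normal light and 10.5 ± 0.202 in high light. The brightest 34 probes of a sample held 48.3% ± 1.29 of its summed signal in normal light and 34.6% ± 0.769 in high light. Among them, 6 to 8 probes per sample stood at the ceiling in normal light and 0 to 2 in high light. What the ceiling does to these shares was not tested. On the deposited scale the median probe was 1.47 higher on the log2 scale in high light. Fold changes of single genes are therefore given after quantile normalisation, relative to the other probes of the array, where the median probe stood at 0.16.

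**Figure D1:**
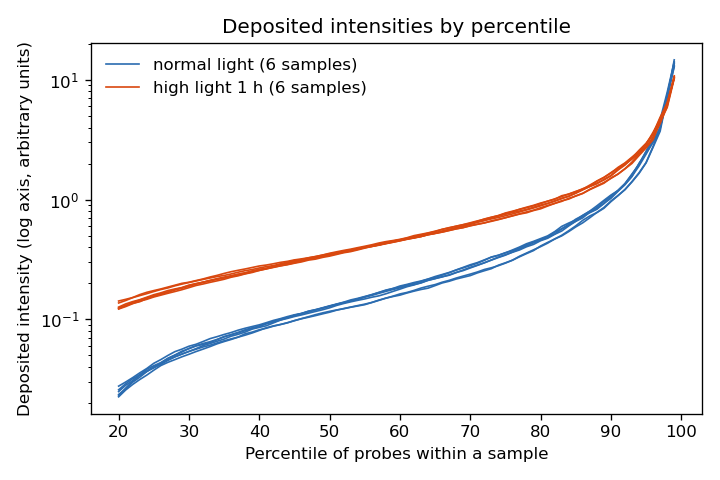
Deposited intensity (log axis, arbitrary units) against the percentile of probes within a sample, 1 line per sample, for the 6 samples of normal light and the 6 of high light. The lines of high light lie above those of normal light at the median (0.338 to 0.357 against 0.115 to 0.130), and the means cross before the 99th percentile (10.5 against 13.7).

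Of the 16 measured members of the fixed lists, 2 rose, 10 fell and 4 did not pass the test. On the deposited scale 4 of the 10 falls turned upwards (5 rises and 6 falls in all), and with samples 1 and 2, 3 and 4, and 5 and 6 averaged 5 of the 10 lost their call. PRK, phosphoribulokinase of the Calvin cycle, fell by 1.89 on the log2 scale after quantile normalisation (SE 0.0951, adjusted p = 1.4e-07). Its deposited intensity went from 3.12 ± 0.250 to 1.14 ± 0.024 (SD, n = 6), a log2 change of -1.45. LHB1B2 (LHCB1.5), a chlorophyll-binding antenna protein, fell by 0.96 (SE 0.204, adjusted p = 0.0032). The peroxiredoxin PRXIIE (AT3G52960) rose by 1.36 (SE 0.160, adjusted p = 6.5e-05). Its deposited intensity went from 0.159 ± 0.036 to 0.972 ± 0.077, a log2 change of 2.64. With the pairs of samples averaged, PRK and PRXIIE kept their calls in limma at larger adjusted p values, 0.0041 and 0.015.

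The ribosomal proteins of the plastid were the fixed list with the most measured members, 6. Of these, 4 fell and 2 did not pass the test, and adjusted over the list alone 5 passed. PRPS6 (AT1G64510) fell by 2.65 (SE 0.298, adjusted p = 4.9e-05) and PRPS10 (AT3G13120) fell by 1.74 (SE 0.184, adjusted p = 3.2e-05), each with no overlap between the groups. PRPL17 (AT3G54210) and PRPL5 (AT4G01310), with log2 changes of -0.49 and -0.44, turned to 0.61 and 0.95 on the deposited scale, and neither kept its call with the pairs of samples averaged (adjusted p = 0.23 and 0.11). PRPL29 (AT5G65220) was listed at 0 in 5 of 6 samples of each group, and PRPL34 (AT1G29070) in 2 of 6 samples of high light (adjusted p = 0.0504, not past the threshold). The list lay lower in high light relative to other probes, with a median log2 change of -1.12 (camera, p = 0.0099) that was -0.28 on the deposited scale (p = 0.030), but the call was lost with an estimated correlation (p = 0.081) and with the pairs of samples as a random block (p = 0.096). Other splits of the samples gave a camera p as small in 9 of 100 cases, the real split included, so chance is not excluded for the list.

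After quantile normalisation, the measured subunits of the photosystems did not move one way. PSBW, a small subunit of photosystem II, rose by 1.06 (SE 0.128, adjusted p = 7.8e-05), from 27.2 ± 2.96 to 54.6 ± 9.36 in deposited intensity, but its change was -0.49 when columns were scaled to a common median. PSBY, another small subunit of that complex, fell by 1.15 (SE 0.128, adjusted p = 4.6e-05). PSAN of photosystem I fell by 0.64 (SE 0.201, adjusted p = 0.027), and its groups overlapped. With samples 1 and 2, 3 and 4, and 5 and 6 averaged, the calls of PSAN (adjusted p = 0.20) and LHB1B2 (0.096) were lost.

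Of enzymes of plastid metabolism, CHLM, a methyltransferase of chlorophyll synthesis, fell by 1.46 (SE 0.316, adjusted p = 0.0034) and FATB, a thioesterase of fatty acid synthesis, fell by 1.32 (SE 0.248, adjusted p = 0.0015). Both directions turn on the deposited scale, where the changes were 0.038 and 0.13, and with the pairs averaged the adjusted p of CHLM was 0.071. SBPASE of the Calvin cycle had a log2 change of 0.36 (SE 0.183, adjusted p = 0.14) and CHLP (AT1G74470) one of 0.049 (SE 0.227, adjusted p = 0.87), neither passing the test, and these went to -0.0025 and -1.04 with a common median.

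The largest rise of a named gene was that of AT4G35660, with a log2 change of 4.58 after quantile normalisation (SE 0.313, adjusted p = 1.8e-06). Its deposited intensity was 0.0906 ± 0.048 in normal light and 4.34 ± 1.25 in high light (SD, n = 6), a log2 change of 5.71. With the pairs of samples averaged, its adjusted p in limma was 0.0032. The next were AT3G18870 at 3.04, AT5G39980 at 2.82, the lactate dehydrogenase gene AT4G17260 at 2.82, AT3G11150 at 2.50, AT4G18180 at 2.50, AT4G21170 at 2.37, AT-HF of histidine synthesis at 2.27, AT4G32060 at 2.203 and AT2G27290 at 2.19, with SEs from 0.229 to 0.428. All 10 had a higher mean log2 value in high light under each of the 4 scalings, but with a common median AT4G32060 stood at 1.42 and AT2G27290, no longer called there, at 0.48. AT2G27290 was the brightest of them, at 11.3 ± 3.68 in normal light and 43.0 ± 11.1 in high light. In normal light AT4G35660, AT3G18870, AT5G39980, AT4G17260, AT3G11150 and AT-HF had mean deposited intensities of 0.0618 to 0.0913. These lay below the median of that group, 0.124, so the sizes of these rises rest on dim values. The remaining rises started above that median.

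The largest fall after quantile normalisation was that of AILP1, at -3.85 on the log2 scale (SE 0.520, adjusted p = 1.6e-04). AILP1 went from 0.166 ± 0.070 to 0.0467 ± 0.025 in deposited intensity, a log2 change of -1.92. It was followed by AT1G76450 at -3.61, AT4G05030 at -3.36, AT4G02580, a subunit of mitochondrial complex I, at -2.96, AT1G50000 at -2.82, AT3G27110 at -2.70, PRPS6, AT5G59060 at -2.53, AT1G62780 at -2.37 and AT1G32160 at -2.28, whose call was lost with the pairs of samples averaged (adjusted p = 0.066). In high light the mean deposited intensities of AILP1 and AT3G27110 (0.0303) lay below the 10th percentile of that group, 0.0509. The sizes of both falls therefore rest on values near 0, while the other falls ended above that percentile. By the measure used for the rises, all 10 ended below the median of their group, 0.348, at 0.0303 to 0.326. The sizes of the other falls thus rest on dim values too. On the deposited scale 9 of the 10 also had a lower mean log2 value, though AT1G62780, at -0.66, was not called there. The change of AT3G27110 was 0.20 on that scale, -0.29 with cyclic loess and -1.29 with a common median, and it was called on none of these 3. AT4G24090, singled out after its values were seen, was listed at 0 in all 6 samples of normal light and at 0.313 to 0.512 in high light. It was 1 of 4 named probes, and of 15 probes in all, at 0 in each normal light sample and above 0 in each high light sample. The lowest high light values of the other named ones, AT1G32220, AT4G09970 and AT5G48130, were 9.9e-05, 0.021 and 0.0023. The opposite held for 0 probes, but zeros were more frequent in normal light throughout, with 396 to 470 per sample against 167 to 209.

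**Figure D2:**
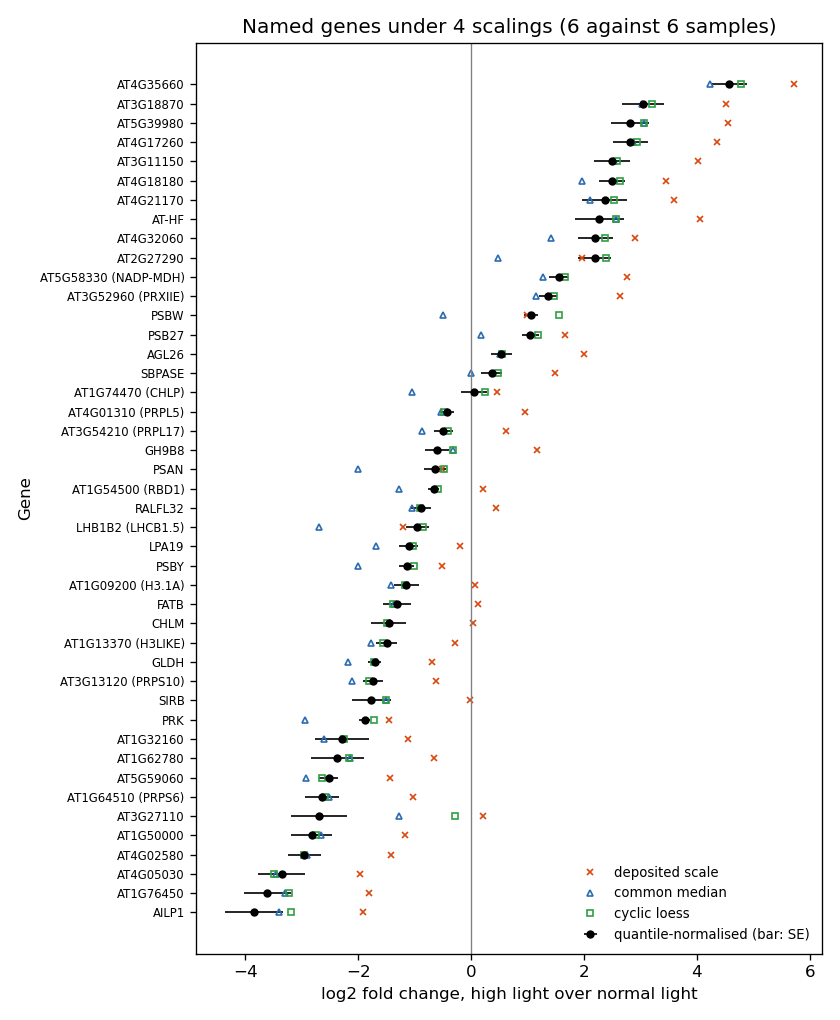
log2 fold change, high light over normal light, of the named genes above 0 in all 12 samples, with the SE after quantile normalisation (black) and the values under the other 3 scalings. PRK lies left of 0 and AT4G35660 right of 0 in each scaling, while PSBW crosses to -0.49 with a common median and CHLM to 0.038 on the deposited scale.

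Over all probes, limma called 1300 of 3439 at an adjusted p under 0.05, 543 higher and 757 lower in high light. Of the 692 probes with a single gene, 126 rose and 147 fell. The values of the groups did not overlap for 1056 probes, where chance alone separates 0.216% of probes if the 12 samples are independent. With samples 1 and 2, 3 and 4, and 5 and 6 averaged, 759 probes were called, 330 higher and 429 lower, and 725 of these were among the 1300 with the same direction. The split into higher and lower followed the scaling, with 1698 and 194 on the deposited scale, 394 and 911 with a common median, and 577 and 615 with cyclic loess, and 350 higher and 182 lower probes were called under each of the 4.

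**Figure D3:**
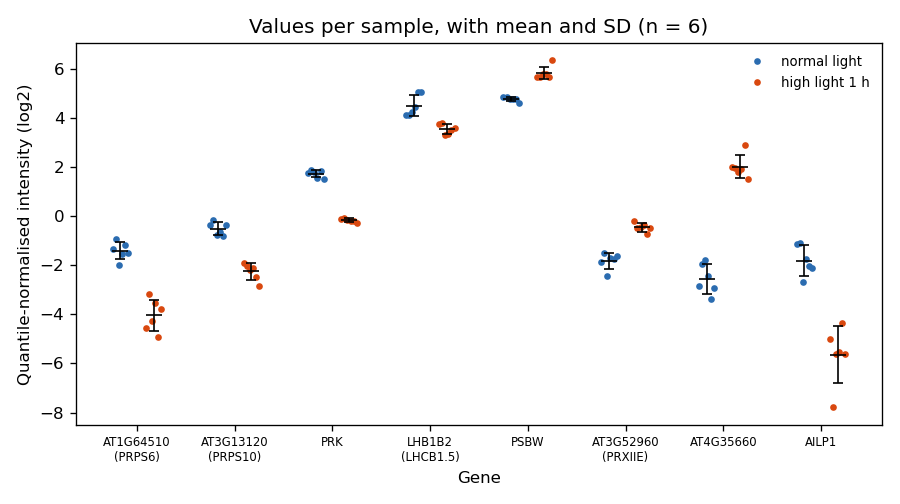
Quantile-normalised intensity (log2) of 8 genes in each of the 6 samples of normal light and the 6 of high light, with the mean and SD as black bars. PRPS6, PRPS10, PRK, LHCB1.5 and AILP1 lie lower in high light and PSBW, PRXIIE and AT4G35660 higher, with no overlap; the direction of PSBW turns with a common median (-0.49).

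The correlation of log2 values across probes, which are not independent replicates, averaged 0.482 between groups (0.445 to 0.523). Within a group it averaged 0.713 for samples 1 and 2, 3 and 4, and 5 and 6, and 0.613 for the other pairs (0.450 to 0.771), so that the ranges overlapped. With values under 0.05 raised to 0.05, a floor chosen after the data were seen, they did not (0.848 to 0.953 for these pairs, 0.747 to 0.781 between groups). Among all 225 ways to pair the 6 samples within both groups, this one had the highest mean correlation (exact permutation test, p = 0.0044, the smallest it can give). That p takes the pairing as given, and the test was chosen after the data were seen.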

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

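The test of the pairs of samples was chosen after the data were seen. In 9 of 92 groups of 6 values, 1 sample stood far from the other 5, where chance alone gives about 1 in 20. The gap to the nearest sample over the whole range, given in parentheses, was taken on log2 values. PSBW had such a sample in both groups, each time number 6. In high light that sample had a normalised intensity of 82.5 against 51.8 to 56.8 in the others (0.804), and in normal light 24.9 against 27.8 to 29.1 (0.704). Those others were tied at 51.8 or 56.8, and at 27.8 or 29.1, because quantile normalisation gives each rank 1 value. For PSBW the gaps are thus steps between ranks of bright probes. High light sample 6 was also apart for PSBY, at 0.658 against 0.836 to 0.963 (0.629), and for GLDH, at 0.337 against 0.244 to 0.272 (0.667). Normal light sample 6 was apart for GH9B8, at 0.0950 against 0.149 to 0.194 (0.626). The remaining ones were AT4G35660 in high light sample 5, at 7.59 against 2.85 to 4.00 (0.655), AILP1 in high light sample 2, at 0.0045 against 0.0203 to 0.0496 (0.627), AGL26 in normal light sample 1, at 0.152 against 0.249 to 0.294 (0.750), and CHLP (AT1G74470) in normal light sample 3, at 1.04 against 1.995 to 2.92 (0.631).

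The likeness of samples with neighbouring numbers was weighed as a chance pairing. The exact permutation p of 0.0044 argues against that only for a pairing named beforehand. This pairing was not named by the rule and was tested after the data were seen, so chance is not excluded. Repeat measurements of 1 RNA, shared plants or a shared day of work would each give such pairs, and the labels do not tell which, if any, applies. No biological explanation was tested. If the pairs are repeat measurements, 3 against 3 is the fitting comparison, with 759 calls in place of 1300.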

How the results depend on the processing

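The floor of 0.05, the restriction to probes above 0 and the fit without samples 5 and 6 were chosen after the data were seen. The total of 1300 calls moved by over 1.5 times with the pairs averaged (759; 330 higher, 429 lower) and with a threshold of 2-fold (818; 434 lower). The fold threshold lowers the count by construction. Fewer samples alone do not account for 759, since averaging samples 1 and 4, 2 and 5, and 3 and 6 gave 1184 calls (518 higher, 666 lower). The deposited scale gave 1698 higher and 194 lower, where the median probe shifted by 1.47. Leaving out 1 sample gave 1190 to 1325 calls, 479 to 575 higher and 706 to 761 lower. The median of the plastid ribosomal list, -1.12, was -0.28 on the deposited scale, -1.49 with a common median and -1.15 with cyclic loess, each still called by camera. Leaving out 1 sample kept it at -1.96 to -1.06 (p from 0.0061 to 0.020), and its call ended with an estimated correlation (-1.12, p = 0.081) and with pairs as a random block (-1.12, p = 0.096). The mean correlation of neighbouring numbers, 0.713, was 0.867 with an offset, 0.941 with the floor of 0.05 and 0.944 over probes above 0. Subtracting a 1% background moved nothing, because that quantile was 0 in every sample. Alternatives meant for kept deposited values or averaged samples as the main setting were not needed, and without dim probes the histone list had too few members to test.

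On the deposited scale, changes turned upwards for AT3G27110 (0.20), CHLM (0.038), FATB (0.13), GH9B8 (1.17), RALFL32 (0.44), AT1G09200 (0.070), PRPL17 (AT3G54210, 0.61), PRPL5 (AT4G01310, 0.95) and RBD1 (AT1G54500, 0.20). With a common median, PSBW (-0.49), SBPASE (-0.0025) and CHLP (AT1G74470, -1.04) turned downwards, and CHLP also did so without normal light sample 3 (-0.15). The cause was not tested beyond the shift of the median. With the pairs averaged, 9 of 45 named genes lost their call. For 6 uncalled lists the median or the direction of the test turned. On the deposited scale the medians of the thylakoid, pigment and histone lists went from -0.65, -0.40 and -0.94 to 0.11, 0.45 and 0.033, with the test still pointing downwards, and that of the histone list was 0.048 without normal light sample 2. For flower, pollen and meristem genes the median, 0.20, went to -0.055 with the floor, without dim probes or over probes above 0 and to -0.054 with an offset, while with fry and with averaged pairs it stayed at 0.20 and only the test pointed downwards. For glycosyl hydrolase family 9 the median, -0.061, went to 0.15 with a common median, 0.17 with cyclic loess, 1.64 on the deposited scale and 0.11 without samples 5 and 6. Only the test turned, upwards, with the floor, without dim probes or with trend and robust settings (median -0.061), with an offset (-0.065) and without normal light sample 2 (-0.071), and leaving out 1 normal light sample gave medians of -0.18 to 0.068. For plastid carbon metabolism the median, 0.28, went to -0.12 with a common median, and with fry, with trend and robust settings and with pairs as a random block it stayed at 0.28 and only the test pointed downwards.

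Taken singly, the sample numbers did not pair the groups. Deviations of same-numbered samples correlated at -0.0063 to 0.065, and 4 of 12 samples correlated best with their own number. With the numbers as a replicate block, 1195 probes were called by limma, 490 higher and 705 lower, and the plastid ribosomal list stayed at -1.12 (camera in limma, adjusted p = 0.011).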

Other observations

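The 7 lists described first were written after the probe names were known and before any test. Several reuse genes given above, so their counts and tests are not separate evidence. The thylakoid list holds PSBW, PSBY, PSAN and LHB1B2, and the thiol list holds PRXIIE. The pigment list holds CHLM and CHLP, and the carbon list holds PRK, SBPASE and NADP-MDH, which is also in the thiol list. The tests of sample splits, of the broad rise and of position on the array were written after the data were seen. Among 6 enzymes of thiol redox and ascorbate metabolism, 2 rose, 1 fell and 3 did not pass the test (camera, adjusted p = 0.63). NADP-MDH (AT5G58330), an NADP-dependent malate dehydrogenase of the plastid, rose by 1.55 after quantile normalisation (SE 0.169, adjusted p = 3.9e-05). Its deposited intensity went from 0.177 ± 0.050 to 1.16 ± 0.127 (SD, n = 6), a log2 change of 2.76. GLDH, the enzyme of the final step of ascorbate synthesis, fell by 1.71 (SE 0.114, adjusted p = 1.5e-06). Its deposited intensity went from 0.639 ± 0.069 to 0.394 ± 0.055, a log2 change of -0.70. With the pairs of samples averaged, the adjusted p of GLDH in limma was 0.0075. Among 12 thylakoid subunits and assembly factors, 3 rose, 5 fell and 4 did not pass (adjusted p = 0.63). Both PSB27, which rose by 1.05 (SE 0.151), and LPA19, which fell by 1.11 (SE 0.161), act in photosystem II assembly, but the first was at 0.18 with a common median and the second at -0.20 on the deposited scale, neither called there. RBD1 (AT1G54500) fell by 0.66 (SE 0.0944), but its change was 0.20 on the deposited scale. PYG7 (AT1G22700), of photosystem I assembly, was listed at 0 in 3 of 6 samples of normal light and at 0.420 to 0.638 in high light, and its call as 1 of the 3 rises was lost with the pairs of samples averaged (adjusted p = 0.16).

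Of the other lists, plastid pigment and tetrapyrrole enzymes had 2 of 5 members that fell (adjusted p = 0.63), among them SIRB of sirohaem synthesis at -1.78 (SE 0.345), which was -0.013 and not called on the deposited scale. Plastid carbon metabolism had 1 rise and 1 fall in 4 members (adjusted p = 0.88). Histone H3 and cell cycle genes had 2 falls in 4 members (adjusted p = 0.63), AT1G13370 at -1.50 and AT1G09200 at -1.15, which were at -0.29 and 0.070 on the deposited scale and not called there. Glycosyl hydrolase family 9 had 1 fall in 4 members, GH9B8 at -0.60 (adjusted p = 0.044, and 0.16 with the pairs of samples averaged), which turned to 1.17 on the deposited scale, and for this list the camera adjusted p was 0.88. Flower, pollen and meristem genes had 1 rise, AGL26 at 0.54 (not called with the pairs averaged, adjusted p = 0.16), and 1 fall, RALFL32 at -0.88 with 0.44 on the deposited scale, in 7 members (adjusted p = 0.88). By fry, which does not compare a list with other genes, the thylakoid, pigment, carbon and histone lists passed at adjusted p values of 3.0e-04, 0.024, 0.0019 and 0.026, each on balance lower, although the median of the carbon list was 0.28.

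Of 100 splits of the 12 samples into 6 and 6, 1, the real one, called as many as 1300 probes, and the highest of the others called 1, so chance is excluded for the number of calls if the 12 samples are independent. If samples 1 and 2, 3 and 4, and 5 and 6 are repeats of 1 RNA, 10 splits remain, too few for a share under 0.05. The real one then gave 759 calls and the highest of the others 4. For the plastid ribosomal list, 9 of 100 splits gave a camera p as small as 0.0099, and the smallest of the others was 8.7e-04.

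The broad rise of dim and middle intensities in high light was weighed against 3 technical explanations. A single factor per sample would move all percentiles alike, but the ratio of high to normal light was 2.80 at the median and 0.765 at the 99th percentile. A constant background would add alike, but the difference at the 90th percentile was 4.58 times that at the 25th. A larger share of signal in the brightest probes of normal light leaves a ratio of the medians of 1.89 after scaling to the sum without them. A change of the RNA population, and a difference in hybridisation or scanning between the groups, stay open, since the labels give no batch.

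Fold changes of probes 12 numbers apart on the array resembled each other (r = 0.093 over probes above 0 in all samples, permutation p = 0.0004). This lag had the highest r of those up to 36, and the p is for it alone, without allowance for that choice. Mean levels were alike too, with r = 0.217 at 12 numbers apart and 0.178 at 6. The 30 lags up to 36 that are no multiple of 6 lay between -0.056 and 0.060, and of the other multiples of 6, lags 18 and 30 gave 0.090 and 0.062, and lags 6, 24 and 36 gave 0.048, -0.0098 and 0.025, within that range. Signal spilling over from bright spots may be one source, and it predicts the likeness above all in pairs far apart in level. Over pairs 6 or 12 numbers apart, r was 0.029 (95% interval -0.074 to 0.132) where levels differed by 8-fold or more and 0.133 (0.073 to 0.192) where they differed by under 2-fold. The intervals overlap, so spill-over cannot be told apart from a layout that places like genes together.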
